A study of Forsythia viridissima with 2 samples.

How the data were processed

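RNA was sequenced from 1 flower library and 1 leaf library of Forsythia viridissima, an ornamental and medicinal shrub of the olive family. Per the labels, both tissues came from plants 2 years old, grown outdoors in a medicinal plant collection, and the labels do not say whether one plant gave both. Poly(A) RNA was fragmented, primed with random hexamers and made into strand-specific libraries, per the labels' protocols. The submitters' processing notes name Trimmomatic, a read trimmer, and RSEM, a program that estimates how many reads came from each transcript, with no versions. The aligner, the assembler and the assembly filters are not given in the sources used here.

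The features are 88491 contigs, which are transcripts put together from reads without a reference genome. They were 224 to 15810 bases long, with a median of 492 bases. The IDs have the form that the Trinity assembler writes, in which contigs of one assembly gene share the part of the ID before the isoform number. By that part the contigs fell into 71044 assembly genes, of which 8255 held 2 or more contigs and 1 held 28. The RSEM gene IDs in the deposited tables were as many as the contigs, 88491, so each RSEM gene was 1 contig. For that reason the gene level and the isoform level were the same, and every deposited IsoPct, the percent of a gene's transcripts in one isoform, was 0 or 100.

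The deposited files hold RSEM expected counts per contig, which are not normalized. Every expected count was a whole number, so rounding changed no value. How reads shared between contigs were assigned is not given in the sources used here. The authors' TPM, per the file headers, is the expected count divided by the effective length and scaled to one fixed sum per library, and recomputing it from the counts gave values within 0.05% for contigs of 10 TPM or more. The authors' FPKM, per the file headers, is the expected count per kilobase of effective length, scaled by the total count of the library. The deposited table of both tissues held the same FPKM as the library tables for every contig, with 0 differences. Effective lengths were 171.51 bases (flower) and 167.95 bases (leaf) below the contig length, as the median over contigs of 1000 bases or more. For the shortest contig the effective length was 58.58 bases in flower and 61.3 bases in leaf. FPKM and TPM are divided by these lengths, while counts are not corrected for the difference between the tissues.

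The files pair the contig IDs with no gene names, and contig sequences, an annotation and a genome were not used here. The 20 lists of pathway, tissue and reference genes fixed before the data were examined therefore gave no result. Contigs are named by ID, at most 2 per direction, and no genomic position or function is given for them. For the main comparison the counts of single contigs were scaled between the libraries with TMM factors (edgeR 4.0.16, R 4.3.3), giving TMM-scaled CPM. Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.

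With 1 library per tissue no spread between replicates can be had, so no test between tissues was made and no p-value is given. Contigs were compared by a rule of size, set with the other choices before the data were examined: at least 4-fold between the libraries, with at least 20 counts in the higher one. A library at 0 was set to 3 counts, so such a fold is set by that floor. Ratios of single contigs have exact 95% conditional (Clopper-Pearson) intervals, and shares of counts have 95% Wilson intervals. Both cover counting error only. Shares of contigs that lie on one side have 95% intervals from 1000 resamplings of assembly read clusters (contigs with the same TR number), which cover the spread over loci in these libraries and not over plants. In all of these, sequenced fragments without molecular identifiers are not independent molecules. The contigs named are the 2 in each direction with the highest near bound of that interval, among those with at least 100 counts in the higher library. The difference between the tissues has no replicate check.

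The rule was tested on simulated data for flower against leaf, drawn for 88491 contigs at the real mean abundances and library totals. The simulated libraries were scaled by their total counts, without TMM. The contigs to change were drawn from those with at least 20 expected counts in the smaller library before the change. Of the contigs changed 8-fold, 50 of 50 were called in each direction. Of those changed 3-fold, 3 of 50 higher in flower and 0 of 50 higher in leaf passed the 4-fold rule. Of 34609 unchanged contigs that were compared, 3 were called, and the intervals held the true ratio for 95.5% of compared contigs. The simulation had no measured spread between plants or libraries to draw from, since neither tissue had a replicate. These values therefore bear on counting error, and not on how often the rule errs between real flower and leaf samples. They also do not bear on TMM scaling or on the recovery of changed contigs near the count minimum. The alternatives were DESeq2 1.42.0 size factors, other totals, TPM and FPKM with a pseudocount, other count and fold thresholds, and the assembly gene level.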

Results

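Transcript abundance was measured by RNA-seq in the flower and in the leaf of Forsythia viridissima, with 1 library per tissue. The study set these tissues side by side within one of several Forsythia taxa, with secondary metabolism as its subject. The flower library held 8279227 counts and the leaf library 8942023 counts over 88491 assembled contigs. A count of 0, which allows up to 3 counts, corresponds to at most 0.362 CPM of the library total in flower and 0.335 CPM in leaf. Because each tissue had a single library, differences below describe these libraries, and their intervals cover counting error only.

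The first comparison was of which contigs each tissue contained. At 10 counts or more, 40658 contigs were detected in flower and 40315 in leaf, and 34346 of them were detected in both. A further 6312 contigs reached 10 counts in flower alone and 5969 in leaf alone. Most of these one-tissue contigs were thinly covered: 56.7% of the flower set and 62.4% of the leaf set had fewer than 20 counts. Among the one-tissue contigs, 1247 of the flower set had no count in leaf, against 535 of the leaf set with no count in flower. With the leaf counts thinned at random to the flower total, 6748 contigs reached 10 counts in flower alone and 5399 in leaf alone. Over the whole assembly, 6343 contigs had no count in flower and 8312 had none in leaf, although the leaf library was the deeper one. At 0 in both libraries were 361 contigs.

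The leaf library was the more concentrated over its 10, 100 and 1000 most abundant contigs, but not at the single most abundant one, which held 0.724% of counts (0.718 to 0.729%) in flower and 0.671% (0.666 to 0.677%) in leaf. Its 100 most abundant contigs held 15.94% of its counts (95% Wilson interval 15.92 to 15.97%), against 12.38% (12.36 to 12.41%) for the 100 most abundant in flower. The 10 most abundant held 4.69% in leaf and 3.30% in flower, and the 1000 most abundant held 40.4% and 35.3%. Counted from the most abundant contig down, 1869 contigs held 50% of the leaf counts and 2421 held 50% of the flower counts.

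**Figure D1:**
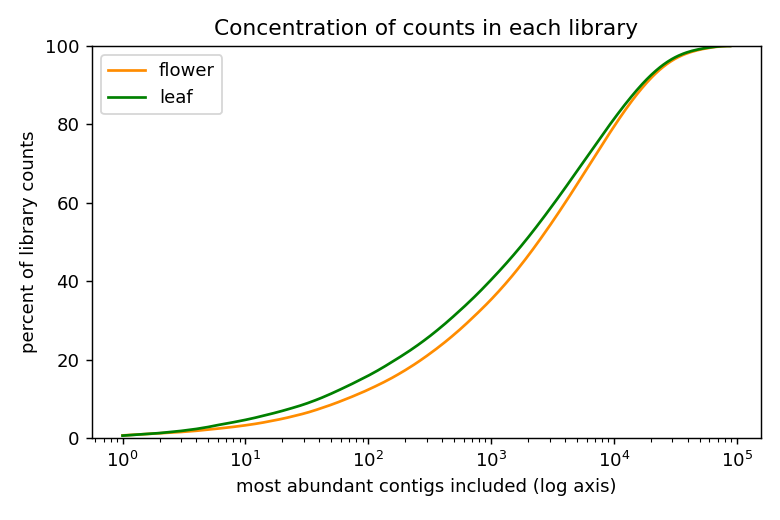
Cumulative percent of library counts (y axis) held by the most abundant contigs of each library (x axis, number of contigs, log axis). The leaf curve lies above the flower curve at 100 contigs, with 15.94% against 12.38%.

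Among the 5 most abundant contigs of each library, 1 was shared. A contig of 6519 bases ranked 1 in flower, with 59911 counts, and 4 in leaf, with 45506 counts. Its TMM-scaled ratio of flower to leaf was 1.35 (95% interval 1.33 to 1.37). The contig at rank 2 in flower, of 1401 bases, had 46693 counts there and 205 in leaf, a ratio of 233 (203 to 269). The contigs at ranks 3 and 5 in flower were 4.53-fold (4.40 to 4.66) and 22.9-fold (21.6 to 24.4) higher there than in leaf.

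In leaf the leading pair were contigs of 753 and 793 bases, with deposited FPKM of 11477.18 and 10370.02. Both were also abundant in flower, at ranks 62 and 65, and they were 8.33-fold (8.13 to 8.54) and 8.27-fold (8.06 to 8.48) higher in leaf. The contig at rank 3 in leaf, of 2655 bases, was at rank 91 in flower and 8.84-fold (8.60 to 9.10) higher in leaf. The one at rank 5, of 2056 bases, was 39.9-fold (37.5 to 42.4) higher in leaf. The highest FPKM of any contig was 4587.08 in flower and 11477.18 in leaf.

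The main comparison asked how far abundance differed between the tissues, contig by contig. Of 36828 contigs with at least 20 counts in one library, 4259 were at least 4-fold higher in flower and 3951 at least 4-fold higher in leaf. Within 4-fold were 28618 contigs, 77.7% of those compared, and 54.6% lay within 2-fold. The compared contigs held 97.4% of flower counts and 97.6% of leaf counts. The median log2 ratio of flower to leaf was 0.04, which equals the log2 size ratio set by the TMM scaling, with quartiles at -0.88 and 0.88. The other 51663 contigs had fewer than 20 counts in both libraries, and at that depth a 4-fold difference was not assessed.

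The contigs higher in one tissue carried a large part of that tissue's counts. Those higher in flower held 23.0% (23.0 to 23.1%) of flower counts and 1.83% (1.82 to 1.84%) of leaf counts. Those higher in leaf held 26.4% (26.4 to 26.5%) of leaf counts and 3.71% (3.70 to 3.73%) of flower counts. The median fold of the flower group was 10.3 and that of the leaf group 7.55, with contigs at 0 in the other tissue set to 3 counts. No counts at all in the other tissue were found for 633 contigs of the flower group and 187 of the leaf group.

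**Figure D2:**
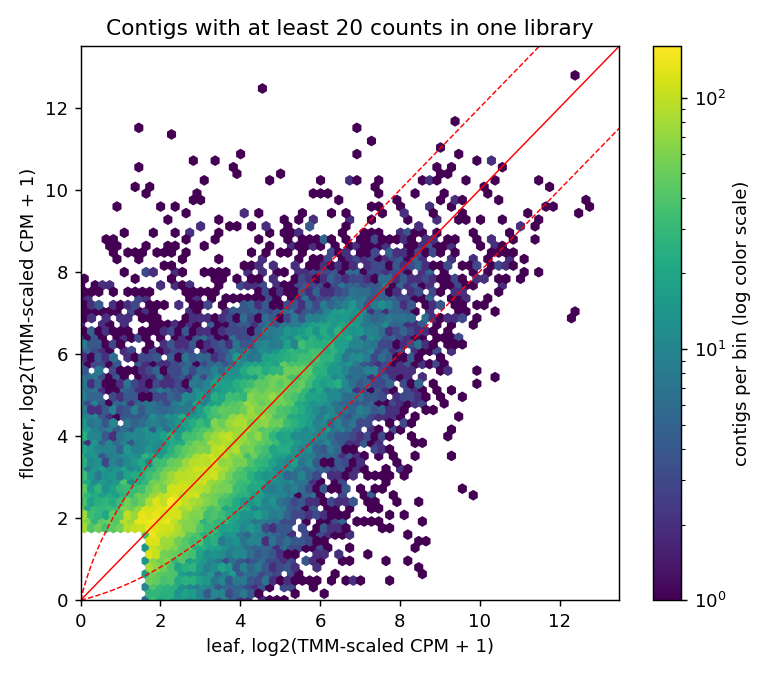
Density of contigs by abundance in leaf (x axis) and flower (y axis), both as log2(TMM-scaled CPM + 1), for the 36828 contigs with at least 20 counts in one library. Color gives contigs per bin on a log scale, the solid line marks equal CPM and the dashed lines mark 4-fold, past which lie 4259 contigs on the flower side and 3951 on the leaf side, with contigs at 0 set to 3 counts for that count.

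The directions parted as the fold grew. At 2-fold or more, 8312 contigs were higher in flower and 8404 higher in leaf. At 10-fold or more the numbers were 2196 and 1468, at 50-fold 589 and 177, and at 100-fold 307 and 54. The small excess of flower contigs at 4-fold, 51.9% of those past the threshold, shrank to 50.6% with DESeq2 size factors and rose to 54.2% when libraries were scaled by their totals. The flower share at 4-fold was 50.4% at a minimum of 100 counts and 55.4% with the near bound of the counting interval past 4-fold. With TPM and a pseudocount of 1 it was 58.4%. At 10-fold the flower share was 59.9%, and it stayed between 58.6% and 62.5% over 6 scalings.

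**Figure D3:**
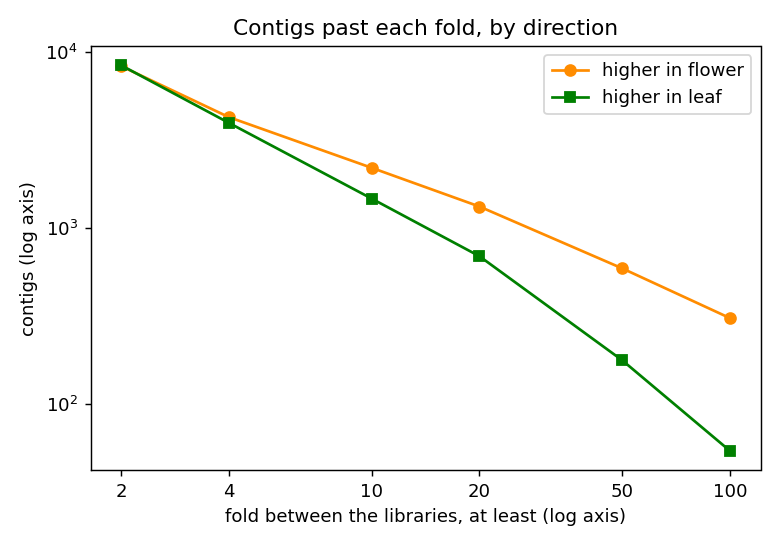
Number of contigs (y axis, log axis) at or past each fold between the libraries (x axis, log axis), for contigs higher in flower (circles) and higher in leaf (squares). The curves meet at 2-fold, with 8312 and 8404 contigs, and part to 307 and 54 contigs at 100-fold.

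By the rule set beforehand, the contigs with the firmest differences were TR23140|c0_g1_i1 and TR5289|c0_g1_i1 for flower. TR23140|c0_g1_i1, of 1084 bases, had 25362 counts in flower and 14 in leaf. Its FPKM was 3357.11 and 1.71, and its scaled ratio was 1856 (1106 to 3396), a log2 ratio of 10.86. By counts it was at rank 4 in the flower library. TR5289|c0_g1_i1, of 1786 bases, had 1911 counts in flower and none in leaf. Set against the floor of 3 counts its ratio was 653. The lower limit of its exact 95% interval was 530, so at that confidence it was at least 530-fold higher in flower. On the log2(FPKM + 1) scale, which shrinks folds where a value is low, the log2 ratios of the pair were 10.28 and 7.17. For TR5289|c0_g1_i1 the log2 ratio from counts was 9.35, with the floor of 3 counts in leaf.

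For leaf the rule gave TR35387|c0_g1_i1 and TR29818|c0_g1_i1. TR35387|c0_g1_i1, of 917 bases, had 3298 counts in leaf and 4 in flower, which is 805-fold higher in leaf (314 to 2955). TR29818|c0_g1_i1, of 1599 bases, had 1942 counts in leaf and 3 in flower, which is 632-fold (216 to 3066). On the log2(FPKM + 1) scale their log2 ratios were -8.22 and -6.93, against -9.65 and -9.30 from counts. Each of these 4 contigs was the only one under its assembly gene name.

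Under TMM scaling, the excess of flower contigs at 4-fold lay among the shorter contigs. It also lay mainly at low counts. With 20 or more but under 100 counts in the higher library, 2140 were higher in flower and 1868 in leaf. With 100 or more but under 1000 counts the numbers were 1735 and 1661, and with 1000 or more they were 384 and 422. Length and count were not separated. Under 1000 bases, 2007 contigs were higher in flower and 1693 in leaf, while at 1000 bases or more 2252 were higher in flower and 2258 in leaf. Under 500 bases the numbers were 534 and 382, which are 17.9% and 12.8% of those compared. The count minimum kept 6.7% of contigs under 500 bases and 52.4% of those of 500 bases or more but under 1000. The contigs kept are a selected part of these lengths, so their shares are not set against those of longer contigs. Of contigs of 1000 bases or more but under 2000, 94.3% were compared, and 10.7% of these were at least 4-fold higher in flower and 10.6% in leaf. Of those of 2000 bases or more, 99.4% were compared, and 6.9% were higher in flower and 7.2% in leaf.

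Across the 36828 compared contigs, abundance in flower and leaf was correlated, with Pearson's r of 0.64 and Spearman's rho of 0.63 on log2(CPM + 1). This is a correlation across contigs, which are not independent replicates, so no p-value is attached to it. With at least 100 counts in one library the values were 0.36 and 0.40, and with all contigs they were 0.85 and 0.74. Each minimum removes contigs that are low in both libraries, which by itself can lower the correlation. Values at unlike minimums are therefore not set against each other.

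The last comparison concerned contigs of one assembly gene. Of 6833 assembly genes with 2 or more contigs and at least 20 counts in each tissue, 76 (1.1%) had a contig with 60% or more of the gene's counts in one tissue and under 40% in the other. For 46 of the 76 the summed counts of the assembly gene lay within 4-fold between the tissues. Contigs past 4-fold in both directions under one name were found in 7 assembly genes. In contrast, 450 assembly genes had 2 or more contigs higher in flower and none higher in leaf, and 477 had 2 or more higher in leaf and none higher in flower. Contig shares were taken from counts without a correction for length.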

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

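Of 106 alternative values, 57 stayed within 1.5 times a count, within the counting interval of a share or fold, or at the same correlation to 2 decimals, and 49 moved further. None of the 106 reversed the sign of a single value, but this says little. Counts and shares of counts cannot change sign, and the named contigs lay far from equal abundance. The larger group at 2-fold was leaf and at 4-fold flower. The levels named gene and isoform gave identical values, since each RSEM gene was 1 contig, so the isoform values among the 57 repeat the main ones. The assembly gene level and the factors from contigs of at least 20 counts were added after seeing the data. The contigs higher in flower and in leaf numbered 7680 and 6421 with no count minimum, 2119 and 2083 at 100 counts, 8312 and 8404 at 2-fold, and 2196 and 1468 at 10-fold. With the near bound of the counting interval past 4-fold they numbered 2758 and 2223. With TPM and a pseudocount of 1, contigs higher in leaf numbered 2521, and those higher in flower 3546. Detection in flower, leaf and both was 82148, 80179 and 74197 contigs at 1 count, 14742, 14505 and 11021 at 100 counts, and 74798, 71802 and 59733 at an FPKM of 1. Detection in flower alone and leaf alone was 3721 and 3484 at 100 counts, and 15065 and 12069 at an FPKM of 1. The share of counts in flower and leaf was 3.30% and 4.69% for the top 10 contigs, 35.3% and 40.4% for the top 1000, 12.1% and 15.5% of TPM for the top 100, and 13.8% and 17.4% for the top 100 assembly genes. Pearson's r and Spearman's rho were 0.845 and 0.738 with no count minimum, 0.548 and 0.513 on FPKM, 0.357 and 0.401 at 100 counts, and 0.656 and 0.669 for assembly genes. Assembly genes with a different main contig numbered 29 at 100 counts in each tissue and 5 at 80% and 20%. The median log2 ratio was 0.111 with totals, 0 with DESeq2 size factors, 0.011 with those from contigs of at least 20 counts, and 0.015 with TMM from the same contigs. DESeq2 size factors over all contigs were 1 in both libraries. Each of these medians equals the log2 size ratio of leaf to flower under its scaling, so the shifts of the median follow from the scaling alone. The cause of the other shifts was not tested. The fixed gene lists gave no value under any setting, because no contig had a name. Depth limits the 51663 contigs under 20 counts in both libraries, which were 58.4% of the assembly. No paired analysis was possible because each tissue had 1 library.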

Other observations

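The tests of leaf RNA in the flower library, and the intervals over resampled read clusters, were chosen after the results they bear on were seen. The other tests were written before their own results, but after the files were seen, among them those at the assembly gene level and over scalings from contigs of at least 20 counts.

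Contigs that share an assembly gene name mostly lay on the same side. The hypothesis was that such contigs follow one tissue pattern. Among 2437 pairs of contigs past 4-fold under one name, in 934 assembly genes, 99.5% went in the same direction, against 48.1 to 52.1% for random pairs (central 95% of 1000 draws). The 8210 contigs past 4-fold are therefore not that many independent loci, and at the assembly gene level 3361 were higher in flower and 3049 in leaf. Contigs under one name can share reads. Contig sequences were not used here, so the part of the 99.5% that comes from shared reads was not assessed.

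The excess of flower contigs among large folds was the pattern most in need of a second look. Past 10-fold, 2196 contigs were higher in flower and 1468 in leaf. Scaling, short or thin contigs and the correction for 2% leaf RNA were checked at this fold only. The wider gaps at 50-fold and 100-fold were not put to these checks. The choice among 6 scalings is argued against as the cause, since the lowest flower share over them was 58.6%. Their log2 size ratios of leaf to flower spanned only 0 to 0.111, so a larger size difference between the libraries was not tested. Short or thinly covered contigs did not account for the excess: among those of 1000 bases and 100 counts or more the flower share was 59.1%. Leaf RNA making up 2% or more of the flower library would cap the leaf excess at 50-fold, yet 33 contigs had counting intervals past 50-fold higher in leaf, against 249 higher in flower. With 2% leaf RNA a true 10-fold excess would be measured as 8.47-fold in leaf and 9.82-fold in flower. Counting the 1751 leaf and 2235 flower contigs past those folds still left a flower share of 56.1% (95% interval over resampled read clusters 54.1 to 58.2%). A smaller share is thus argued against as the whole cause at 10-fold. At 2% the excess fell from 2196 against 1468 to 2235 against 1751. The 33 contigs argue against a share as large as 2%. A part of the excess no larger than that fall therefore stays open to a smaller share. Transcripts from another organism and a difference between the tissues, which 1 library each cannot separate from a difference between samples, stay open and untested.

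At 4-fold the excess was small, with 4259 against 3951 contigs. Under TMM scaling it was absent at 1000 bases or more, with 2252 against 2258. Counting error gave at most 10 contigs past 4-fold in 20 random splits of the summed counts, which bears on the size of the folds in these libraries and does not decide about the excess. Scaling cannot be told apart from a tissue difference here, because the flower share fell to 50.6% under the least favorable of the 3 scalings tested. Repeated counting of contigs under one assembly gene name is argued against as the whole cause, under TMM scaling only. The flower share at the assembly gene level was 52.4% (95% interval over resampled read clusters 51.1 to 53.8%), above the 50% that explanation would need. The bound of 52% written beforehand was stricter than that explanation requires. The assembly gene level was not assessed with DESeq2 size factors, under which the contig-level interval reached below 50%. Contigs of one gene under different names could not be joined without sequences, so repeated counting of those was not tested.

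For the 76 assembly genes whose main contig differed between tissues, counting error was tested as the source. Draws with equal contig shares in both tissues gave 5 to 16 such genes in 20 repeats. For a number of the 76 like those 5 to 16, a difference in contig use cannot be told apart from counting error. The draws do not say which, and 16 is the highest of 20 draws rather than an upper limit. No other technical explanation was tested for the rest, reads shared between contigs among them.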
